A study of Mus musculus with 8 samples.

How the data were processed

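RNA was sequenced from C2C12 mouse myoblasts that were WT or overexpressed AUF1, in total RNA and in RNA of heavy polysomes, with 2 libraries in each of 4 groups. Per the labels, cells were grown in 10% fetal bovine serum and kept for 48 h in 2% horse serum, RNA was cleaned on Qiagen RNeasy columns, and libraries were made from 500 ng RNA with a NEBNext Ultra kit. The libraries titled High, whose molecule is given as cytoplasmic RNA, were read as the heavy polysome fraction. The titles number the replicates 1 and 2, and the library descriptions call the second one Rep3; the title numbers are used here.

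The deposited values are raw counts per gene symbol, 1 column per library, with 23420 lines for genes and 5 summary lines. The submitters' processing notes name cutadapt, Bowtie, Trimmomatic, STAR, SAMtools and the build mm10. Versions of these tools, the counting program, its strand setting and the gene annotation are not given in the sources used here. Reads outside any gene made up 6.04% to 7.23% of counts and reads assigned to more than 1 gene 0.254% to 0.389%, and the summary lines were left out of the totals and tests. Names of 27 genes had been turned into dates, as spreadsheets do with Sept, March and Dec genes. These lines held 0.216% to 0.327% of each library's counts and were kept in the fits but not named. Mymk and Mymx are listed as Tmem8c and Gm7325. Positions come from the GENCODE M21 annotation of mm10, in which 12377 of the tested genes (94.0%) were found by symbol.

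Genes were kept by edgeR's filterByExpr, which left 13167, and libraries were scaled by TMM (trimmed mean of M-values). A quasi-likelihood model with 1 coefficient per group, fitted in edgeR 4.0.16 (R 4.3.3), gave 5 comparisons, namely AUF1 against WT in total and in polysome RNA, their interaction, and polysome against total RNA in each genotype. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes of 1 comparison, and genes with an adjusted p under 0.05 were called. SE is the log2 fold change over the square root of the F statistic, SD is over the 2 libraries of a group, and CPM are counts scaled by TMM to a common library total. Sets were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, over 36 lists of which 34 had at least 5 measured genes, adjusted over the lists of 1 comparison. Of the other lists, 1 had 0 and 1 had 3 measured genes. The name pattern of the histone list also took in H13 and H19, which are not histone genes. That list was kept as fixed and run again without them, a choice made after the data were seen.

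The comparisons, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names Hnrnpd first, then per comparison the 10 largest rises and falls among called genes with a mean log2 CPM of at least 3 and groups that did not overlap. For this part 87 genes were eligible in total RNA and 35 on polysomes, and 1 gene model without a proper name was passed over in each. Up to 4 members with the smallest p are named in a described list, and 15 genes of myogenesis whatever their result. H19, Sepw1, Sfrp2, Igf1, Lgr5, Notum, Tcf7, Sparc, Actb, Bsg, Ctsd and Neb were chosen after their values were seen.

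Differences between replicates 1 and 2 were alike across the groups. The numbers were not treated as pairs in the planned model, since only 2 numbers exist and the labels do not say what they share. The fit with the number as an additive block, and changes within each number, are given beside it. The planned model had 4 residual degrees of freedom and the block 3. The median SE of a log2 fold change was 0.38 in the planned model and 0.27 with the block for the genotype comparisons, and 0.54 and 0.38 for the interaction. Groups of 2 libraries were too small for tests of single outlying libraries or of other splits of the samples.

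Both fits were tested on simulated data with these depths and this split by number, with 100 genes changed 2-fold and 100 changed 4-fold. Means, dispersions and the additive split by number came from the fit with the block, which favours the block. No other genes were changed. For a genotype change the planned model recovered 0% and 0%, and the block 18% and 96% with 4 false calls. For an interaction the planned model recovered 0% and 0%, and the block 3% and 66% with 12 false calls. In the data the planned model called genes changed less than 4-fold in total RNA, such as Pfkm. The 0% for a genotype change is therefore not its power here, and the 0% for an interaction, simulated in the same way, does not measure its power either. A changed list was called in both fits, and 0 of 34 unchanged lists were. Counts were drawn independently for each gene and the unchanged lists were random genes. The simulation therefore does not test how camera treats lists of co-expressed genes. Counting error is small at 25281224 to 34917660 counts per library, and the spread between the 2 replicate numbers exceeded it (chi-square per gene of 389, 513, 375 and 341 in the WT total, AUF1 total, WT polysome and AUF1 polysome pairs).

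Alternatives were DESeq2 size factors, upper-quartile factors, no filter on low counts, a CPM of at least 1 in 2 libraries, DESeq2 1.42.0, limma voom, only the compared groups, the replicate block, the block within genotype, a log2 fold change of at least 1, and each library left out in turn. For lists, an estimated correlation and fry were also run. After the data were seen, 4 were added for genes and lists: the block with a loess correction of each library for GC content (span 0.5), the block with each library left out (for genes and for lists), total-count scaling without the 50 most abundant genes, and the corrected histone list. The scaling left out the same 50 genes, by mean CPM, in every library, and their share of counts was not computed. Each library's own 50 most abundant genes held 10.4% to 15.6% of its counts.

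A planned test asked whether mRNAs with the heptamer TATTTAT in the longest annotated 3' UTR changed as a set, by permutation of gene labels within deciles of UTR length with 100000 resamples, two-sided, in genes with a mean log2 CPM of at least 1. The plan named a difference from mRNAs without the heptamer. The value computed within deciles was the difference from the mean of all mRNAs of the decile. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. Every column of the count table matched a sample, and 0 columns were left out.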

Results

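RNA was sequenced from C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is lowered, after 48 h in differentiation medium. Cells labelled WT were set beside cells that overexpressed AUF1, an mRNA-binding protein encoded by Hnrnpd that binds AU-rich elements in 3' untranslated regions. From each genotype, total RNA and RNA loaded on heavy polysomes, the fraction carrying many ribosomes per mRNA, were sequenced. This gave 4 groups of 2 libraries, 8 libraries in all. Counts assigned to genes came to 25730815 and 25281224 in the WT total libraries (replicates 1 and 2), 34917660 and 26935603 in the AUF1 total libraries, 33860652 and 28367635 in the WT polysome libraries, and 33085255 and 27040518 in the AUF1 polysome libraries. Whether the WT cells carry an empty vector and whether the AUF1 cells are a pool or a clone is not given in the sources used here, so an effect of AUF1 and a difference between the lines are not separated. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

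The replicate number split the libraries of all 4 groups. The first principal component of log2 CPM (counts scaled to a common library total) held 51.8% of the variance and separated replicate 1 from replicate 2, and the second held 32.1% and separated AUF1 from WT. The log2 differences between replicates 1 and 2 of a group correlated with those of each other group across 11159 genes, with Pearson's r from 0.67 to 0.90 (genes are not independent replicates). Sparc, a matrix glycoprotein, stood at 9124 CPM in WT total replicate 1 and 664 CPM in WT total replicate 2, while Actb, cytoplasmic actin, stood at 3504 and 3347 CPM. Values from the fit with the replicate number as a block, and changes within each number, are therefore given beside the unblocked ones.

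**Figure D1:**
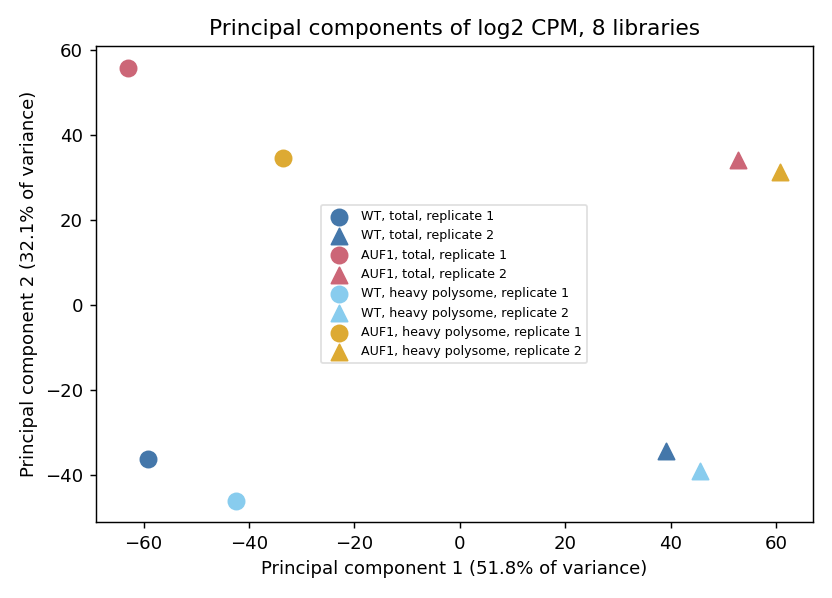
Principal components 1 (51.8% of variance) and 2 (32.1%) of log2 CPM for the 8 libraries, with color for the group and circles and triangles for replicates 1 and 2. Replicate numbers part along the first axis and AUF1 from WT along the second.

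Hnrnpd, the overexpressed gene (mm10 chromosome 5, 99955935 to 99978938), was higher in each AUF1 library than in each WT library. It stood at 64.2 and 99.6 CPM in the WT total libraries and at 448 and 397 CPM in the AUF1 total libraries (means 81.9 ± 25 and 423 ± 36.4, SD, n = 2 each). On heavy polysomes it stood at 106 and 131 CPM in WT and at 549 and 427 CPM with AUF1 (means 119 ± 17.1 and 488 ± 86.2, SD, n = 2 each). The log2 fold change was 2.37 ± 0.32 (SE) in total RNA, with an edgeR adjusted p of 0.0413 (0.000896 with the block). On polysomes it was 2.04 ± 0.32, with an edgeR adjusted p of 0.0608 that did not pass the threshold (0.00184 with the block). The counts are given per gene symbol, so transcripts of the introduced and the endogenous gene are not separated here.

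The comparison of AUF1 with WT in total RNA asks which steady-state mRNAs differ with AUF1 overexpression. Genes of the contractile apparatus were far higher with AUF1. Ckm, muscle creatine kinase, went from 74.7 ± 27.6 to 1639 ± 144 CPM (SD, n = 2 each), and Myh3, embryonic myosin heavy chain, from 122 ± 58.5 to 1365 ± 518 CPM. Myh1, a fast adult myosin, went from 19.1 ± 9.30 to 369 ± 120 CPM. In the other direction, Gcnt1, a glycosyltransferase that builds branched O-glycans, went from 44.3 ± 6.59 to 1.48 ± 0.41 CPM, Axin2, a feedback inhibitor and standard readout of Wnt signalling, from 42.6 ± 0.63 to 5.38 ± 0.76 CPM, and the cytokine gene Il33 from 50.9 ± 6.93 to 3.47 ± 1.69 CPM.

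By edgeR's quasi-likelihood test, 134 of 13167 genes differed in total RNA at an adjusted p under 0.05, 108 higher and 26 lower with AUF1, and each by at least 2-fold. With the replicate block 1730 genes passed, 920 higher and 810 lower. DESeq2 without the block called 885, 523 higher and 362 lower. The 10 largest rises by the naming rule were Ckm, Afap1l1, Myh1, Fbxl22, Ablim3, Filip1, Myom3, Myh3, Nmrk2 and Tceal7, with log2 fold changes from 4.46 ± 0.59 (Ckm, adjusted p = 0.041, 0.000265 with the block) to 3.40 ± 0.46 (Tceal7, adjusted p = 0.0422, 0.000842 with the block). The 9 eligible falls were led by Gcnt1, which fell by 4.90 ± 0.43 on the log2 scale (adjusted p = 0.0399), and the others were Car3 at -4.52 ± 0.64, Nkd2 at -4.07 ± 0.57, Il33 at -3.87 ± 0.42, Fam43a at -3.35 ± 0.29, Slc7a2 at -3.09 ± 0.44, Axin2 at -2.98 ± 0.29, Mcc at -2.55 ± 0.39 and Efhd1 at -2.41 ± 0.34, each with an adjusted p between 0.0399 and 0.0473. Within replicate 1 and replicate 2, Ckm changed by 4.98 and 4.03, Gcnt1 by -5.28 and -4.43, and Axin2 by -2.82 and -3.13. Ckm lies on mm10 chromosome 7 (19404776 to 19422841), Gcnt1 on chromosome 19 (17326141 to 17372844) and Axin2 on chromosome 11 (108920349 to 108950783). Leaving out any 1 of the 8 libraries left 0 genes past the threshold in edgeR without the block, and with the block from 329 (without WT total replicate 1) to 2975 (without AUF1 total replicate 2).

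**Figure D2:**
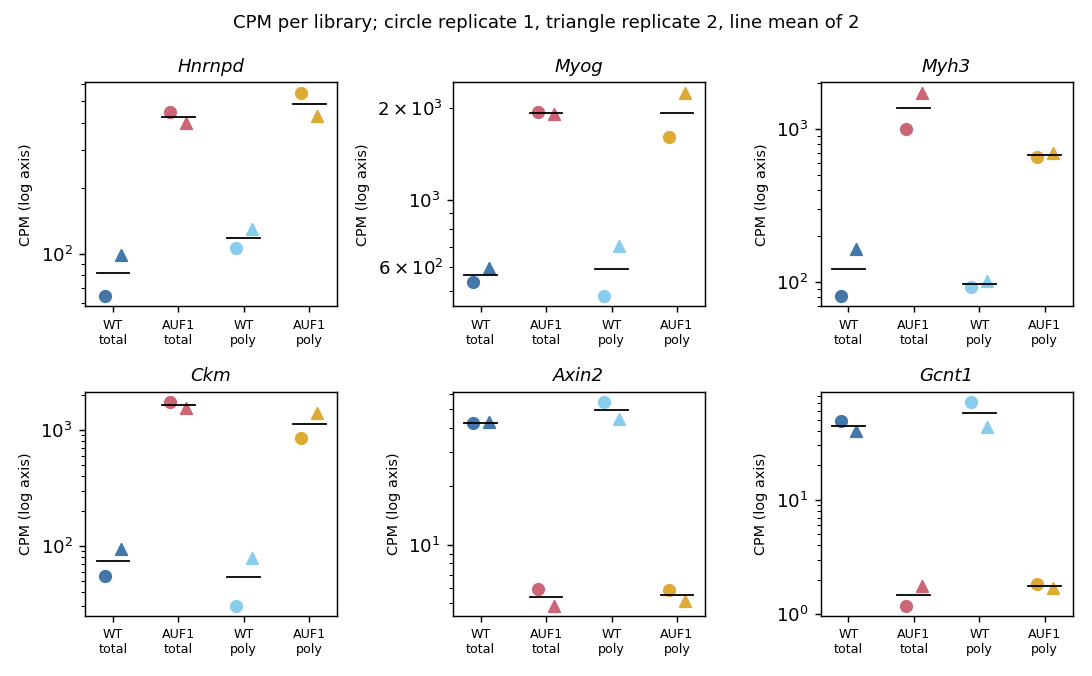
CPM on a log axis of Hnrnpd, Myog, Myh3, Ckm, Axin2 and Gcnt1 in the 8 libraries, by group, with circles for replicate 1, triangles for replicate 2 and a line at the mean of the 2. Hnrnpd, Myog, Myh3 and Ckm are higher, and Axin2 and Gcnt1 lower, in each AUF1 library than in each WT library of the same fraction.

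Among the 36 gene lists fixed beforehand, those for muscle structure moved furthest in total RNA. Sarcomere and Z-disc genes rose as a set, with a median log2 change of 2.41 and all 38 measured members above 0 (limma camera, adjusted p = 2.87e-30; adjusted p = 0.122 with an estimated correlation). In edgeR 13 of the 38 were higher over all genes tested, 31 adjusted over the list alone, and 33 with the block. Unc45b, a myosin chaperone, changed by 3.24 ± 0.31, Myom3, an M-band protein, by 3.60 ± 0.36, and Myoz2, a Z-disc protein, by 2.94 ± 0.32 (adjusted p = 0.0399 for each). The embryonic sarcomere list had a median of 2.66, with 6 of 14 members called, 14 adjusted over the list alone and 14 with the block. Its members included Mybph at 2.65 ± 0.31 and Tnni1, slow troponin I, at 2.70 ± 0.31. Fast fibre genes had a median of 2.76, with 4 of 17 called, 16 adjusted over the list alone and 17 with the block, among them Actn3 at 2.49 ± 0.28 and Tnni2 at 2.53 ± 0.38. Slow fibre genes had a median of 2.41, with 2 of 12 called, 9 adjusted over the list alone and 10 with the block. Camera's adjusted p was 1.6e-18, 1.6e-18 and 1.16e-09 for these 3 lists. With an estimated correlation none of them passed (adjusted p = 0.122 for the fast and slow fibre lists and 0.144 for the embryonic list). Within replicates 1 and 2 the medians were 2.45 and 2.33 for the sarcomere list, 2.82 and 2.46 for the embryonic list, 2.82 and 2.47 for the fast fibre list, and 2.53 and 2.28 for the slow fibre list.

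Genes of calcium handling and excitation rose as a set in total RNA, by a median of 1.98 (camera, adjusted p = 2.77e-10; adjusted p = 0.144 with an estimated correlation). In edgeR 2 of 26 passed, Ryr1, the sarcoplasmic calcium release channel, at 2.30 ± 0.29 and the calcium channel subunit Cacnb1 at 2.22 ± 0.33; 10 passed adjusted over the list alone and 20 with the block. Nuclear genes of oxidative phosphorylation had a median of 0.56 (adjusted p = 1.27e-09; adjusted p = 0.498 with an estimated correlation), with 1 of 78 called, 3 adjusted over the list alone and 15 with the block. The called member was Cox8b, a muscle form of cytochrome oxidase subunit 8, at 3.41 ± 0.45. Glycolysis genes had a median of 0.68 (adjusted p = 0.000311; adjusted p = 0.498 with an estimated correlation), and 4 of 26 were called higher, 9 higher and 2 lower adjusted over the list alone, and 9 higher and 3 lower with the block. The 4 were Pygm, muscle glycogen phosphorylase, at 3.05 ± 0.32, Pgam2 at 2.99 ± 0.30, Pfkm at 1.89 ± 0.29 and Ckm, all muscle forms. Ckm is a creatine kinase and not a glycolytic enzyme, though the list holds it. Heat shock genes had a median of 0.58 (adjusted p = 0.00259; adjusted p = 0.144 with an estimated correlation), with 2 of 18 called higher, 3 higher and 1 lower adjusted over the list alone and 3 higher and 1 lower with the block. The called pair was Hspb3 at 3.67 ± 0.48 and Hspb8 at 1.71 ± 0.26, small heat shock proteins abundant in muscle, whereas the inducible Hspa1b stood at -1.13 ± 0.28 (adjusted p = 0.149, 0.0195 with the block). Without AUF1 total replicate 1 the glycolysis list's adjusted p was 0.0899, and without AUF1 total replicate 2 that of the heat shock list was 0.0665.

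Ribosomal protein genes were higher by a median of 0.33 in total RNA (camera, adjusted p = 0.000175; adjusted p = 0.424 with an estimated correlation) and translation factor genes by 0.37 (adjusted p = 0.00412; adjusted p = 0.424 with an estimated correlation). In edgeR 0 of 76 and 0 of 40 passed, also adjusted over the list alone, and 2 and 2 with the block, among them Rps10 at 1.32 ± 0.24 (adjusted p = 0.0047 with the block) and Eif3d at 0.99 ± 0.25 (0.0248 with the block). Endoplasmic reticulum and amino acid stress genes had a median of 0.47 (adjusted p = 0.007; adjusted p = 0.32 with an estimated correlation), with 0 of 32 called, 4 higher and 1 lower adjusted over the list alone, and 11 higher and 1 lower with the block. Shmt2, mitochondrial serine hydroxymethyltransferase, stood at 1.53 ± 0.31 (0.0061 with the block). Neuromuscular junction genes, the part of muscle that receives the nerve, had a median of 0.57 (adjusted p = 0.0433; adjusted p = 0.498 with an estimated correlation), with 0 of 28 called, 1 adjusted over the list alone, and 8 higher and 1 lower with the block. The acetylcholine receptor subunit Chrnd stood at 2.89 ± 0.93 (0.0016 with the block) and Dok7, which activates MuSK, at 2.49 ± 0.47 (0.0015 with the block). The translation factor list lost its call without WT total replicate 1 (adjusted p = 0.236) or AUF1 total replicate 2 (0.151), and the stress and junction lists lost theirs without AUF1 total replicate 1 (0.186 and 0.277) or WT total replicate 2 (0.0766 and 0.141).

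Lists with lower values in total RNA were those of extracellular matrix, inflammatory cytokines and fibroblast markers. Matrix genes had a median of -0.86 (camera, adjusted p = 0.00223; adjusted p = 0.819 with an estimated correlation), with 0 of 42 called in edgeR, 0 adjusted over the list alone and 15 lower with the block. Col12a1 stood at -2.66 ± 0.54 (0.0012 with the block) and Thbs1, thrombospondin 1, at -1.26 ± 0.30 (0.0082 with the block). The 9 measured fibroblast markers had a median of -1.99 (adjusted p = 0.007; adjusted p = 0.652 with an estimated correlation), with 0 called, 4 lower adjusted over the list alone and 6 lower with the block, among them Dcn at -3.83 ± 1.15 and Mfap5 at -3.94 ± 1.15 (0.000511 and 0.00315 with the block). Cytokine genes had a median of -0.72 (adjusted p = 0.00223; adjusted p = 0.424 with an estimated correlation), with 1 of 20 lower, 2 adjusted over the list alone and 8 with the block, Il33 and Ptx3 among them. Smooth muscle markers, several of which differentiating myoblasts also express, had a median of 1.25 (adjusted p = 0.000319; adjusted p = 0.126 with an estimated correlation), with 1 of 10 called, 7 higher and 1 lower adjusted over the list alone and 6 higher with the block. The called marker was Cnn1, calponin, at 2.57 ± 0.37. Without WT total replicate 1 or AUF1 total replicate 2 the matrix list was no longer called and its direction turned (adjusted p = 0.864 and 0.931), the fibroblast list was not called (0.427 and 0.248), and the cytokine list was not called without AUF1 total replicate 2 (0.0573). Those fits leave the replicate numbers unbalanced. Within replicates 1 and 2 the matrix medians were -0.93 and -0.72, and with the block camera's adjusted p was 8.97e-07 and at most 0.0074 with any 1 library left out. With the block the other 15 lists also kept their calls and directions with any 1 library left out (highest adjusted p = 0.0402). Osteoblast, adipocyte, immune and neuronal or glial markers were not called (adjusted p = 0.327, 0.992, 0.844 and 0.844), with 0 members passing in edgeR in each, and with the block 1 adipocyte marker higher and 1 lower and 1 immune marker lower. Matrix genes also differed between the replicate numbers, by a median log2 of 2.04 in the WT total and 2.01 in the AUF1 total pair.

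**Figure D3:**
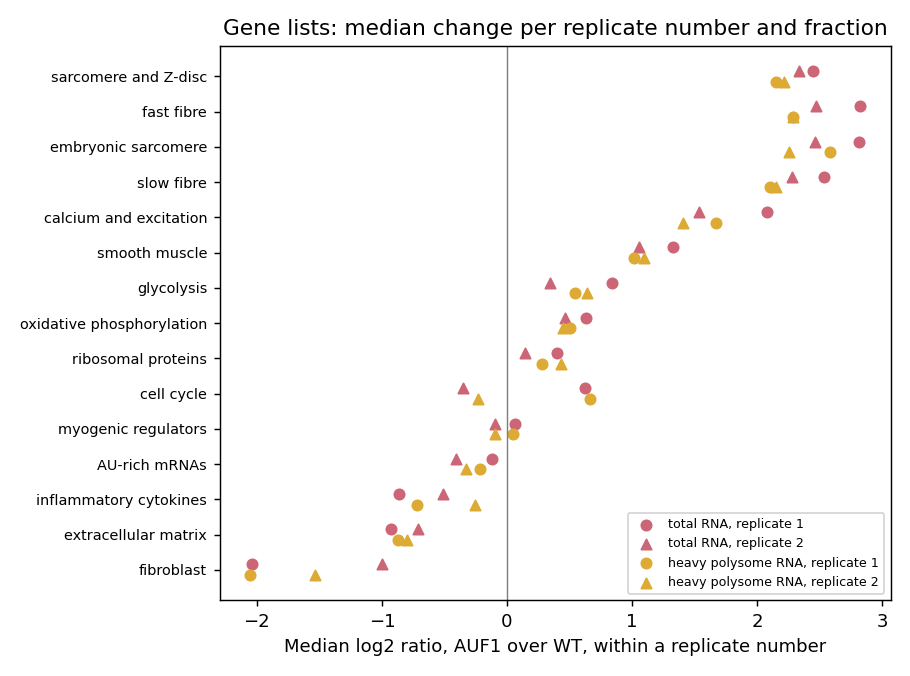
Median log2 ratio of AUF1 over WT within replicate 1 (circles) and replicate 2 (triangles), in total and heavy polysome RNA, for 15 gene lists. The sarcomere, fast fibre, embryonic sarcomere and slow fibre lists lie above 2 in all 4 pairs, and the cell cycle list lies on opposite sides of 0 in the replicates.

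The regulators of myogenesis fixed by name had unlike values. Myog, the factor that drives terminal differentiation (mm10 chromosome 1, 134289989 to 134292548), went from 567 ± 41.3 to 1926 ± 13.2 CPM in total RNA, a log2 change of 1.76 ± 0.29 that missed the threshold in edgeR (adjusted p = 0.0577) and passed with the block (0.0016). Myod1 at 0.37 ± 0.38, Myf5 at -0.78 ± 0.50, Mef2c at 0.14 ± 0.53, Pax7, a satellite cell factor, at 1.22 ± 0.41, Myf6 at -0.69 ± 0.69, Ppargc1a at 1.12 ± 0.72, Musk at 0.56 ± 0.87 and Utrn at 0.17 ± 0.48 passed in neither fit. The fusion genes Mymk and Mymx stood at 2.64 ± 1.70 and 1.81 ± 0.37 and passed with the block only (0.0012 and 0.006), as did Chrna1 at 1.41 ± 1.78 (0.0316) and Ccnd1, cyclin D1, at -1.24 ± 0.32 (0.0225). Cdkn1a, the cell cycle inhibitor p21, rose by 1.78 ± 0.27, from 1293 to 4442 CPM (adjusted p = 0.0462), and Tead4 by 1.95 ± 0.29 (adjusted p = 0.0461). The myogenic regulator list as a whole was not called (adjusted p = 0.688), with 1 of 22 members passing, Tead4, 2 higher and 1 lower adjusted over the list alone, and 3 higher and 2 lower with the block. The cell cycle list was not called either, with 0 of 42 members passing, 2 higher and 1 lower with the block, a median of 0.17 (adjusted p = 0.589) and medians of 0.62 within replicate 1 and -0.35 within replicate 2. The 36 measured mRNAs of the list of known AU-rich mRNAs had a median of -0.17 (adjusted p = 0.106), with 1 member called, Cdkn1a, and 2 higher and 7 lower with the block. Twist1 had 15 counts in WT polysome replicate 1 and 0 in the other 7 libraries and was not tested.

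On heavy polysomes the comparison asks which mRNAs loaded on many ribosomes differ with AUF1 overexpression. Muscle genes were again far higher. Myh1 went from 14.8 ± 2.04 to 202 ± 6.83 CPM (SD, n = 2 each), Klhl41, a sarcomere assembly factor, from 23.9 ± 4.05 to 194 ± 21.1 CPM, and Ckm from 54.2 ± 33.4 to 1122 ± 381 CPM. Gcnt1 went from 57.3 ± 20.1 to 1.76 ± 0.10 CPM and Axin2 from 49.4 ± 7.11 to 5.48 ± 0.51 CPM.

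In edgeR, 46 of 13167 genes differed on polysomes, 37 higher and 9 lower, and 1716 with the replicate block, 882 higher and 834 lower. DESeq2 without the block called 856, 480 higher and 376 lower. The 10 largest rises were Afap1l1 at 4.0 ± 0.46, Ablim3, Fbxl22, Myh1, Tceal7, Tbc1d8, Mylk4, Itgb1bp2, Pgm5 and Arpp21 at 3.06 ± 0.38, with adjusted p from 0.0461 to 0.0492. The eligible falls were Gcnt1 at -5.02 ± 0.43, Il33 at -3.75 ± 0.42, Fam43a at -3.62 ± 0.29 and Axin2 at -3.17 ± 0.29 (adjusted p = 0.0461 for each). Within replicates 1 and 2, Gcnt1 changed by -5.23 and -4.61 and Afap1l1 by 3.92 and 4.01. Myog at 1.70 ± 0.29 (adjusted p = 0.0734), Myh3 at 2.79 ± 0.44 (0.0625) and Ckm at 4.37 ± 0.59 (0.0535) passed with the block only, at 0.0021, 0.000634 and 0.000268. Leaving out any 1 of the 8 libraries left 0 genes in edgeR without the block, and with the block from 592 (without AUF1 polysome replicate 1) to 3011 (without AUF1 total replicate 1).

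The lists moved on polysomes much as in total RNA, with 17 called by camera. Sarcomere and Z-disc genes had a median of 2.21, with 6 of 38 called, 33 adjusted over the list alone and 33 with the block. Embryonic sarcomere genes had a median of 2.47 (2 of 14, 14 and 14), fast fibre genes 2.29 (3 of 17, 14 and 16), slow fibre genes 2.20 (2 of 12, 8 and 10) and calcium and excitation genes 1.61 (0 of 26, 9 and 19), counted in the same order. Camera's adjusted p for these 5 was 6.57e-29, 1.8e-17, 1.7e-16, 4.37e-09 and 2.49e-09, and with an estimated correlation adjusted p = 0.137 for the sarcomere, fast and slow fibre lists and 0.157 for the embryonic and calcium lists. Among other lists, mitochondrial biogenesis genes had a median of 0.42 (adjusted p = 0.0256; adjusted p = 0.353 with an estimated correlation), with 0 of 28 called, 0 adjusted over the list alone and 1 with the block. Replication histone genes had a median of 0.31 (adjusted p = 0.0447; adjusted p = 0.608 with an estimated correlation; 0.0744 with the block), with 0 of 16 called, 0 adjusted over the list alone and 2 with the block, the linker histone genes Hist1h1e and Hist1h1d (0.505 and 0.49 CPM on WT polysomes). The name pattern behind this list also took in H13 and H19, which are not histone genes, and without them the list was not called (14 genes, median 0.35, adjusted p = 0.0516). Matrix genes had a median of -0.84 (adjusted p = 0.000461; adjusted p = 0.738 with an estimated correlation), with 0 of 42 called, 0 adjusted over the list alone and 14 lower with the block, and fibroblast markers -1.91 (adjusted p = 0.00469; adjusted p = 0.608 with an estimated correlation), with 0 of 9, 3 and 6 lower. Cytokine genes had a median of -0.41 (adjusted p = 0.0108, and adjusted p = 0.554 with an estimated correlation), with 1 of 20 lower, 2 adjusted over the list alone and 7 with the block. With the block camera's adjusted p was 5.29e-09 for matrix, 5.29e-05 for fibroblast, 0.0111 for cytokine and 0.0261 for biogenesis genes. Within replicates 1 and 2 the matrix medians were -0.87 and -0.80. Leaving out 1 library without the block leaves the replicate numbers unbalanced. Without WT polysome replicate 1 the matrix, fibroblast, cytokine, biogenesis and histone lists were not called (adjusted p = 0.263, 0.139, 0.162, 0.171 and 0.162), and without AUF1 polysome replicate 2 the matrix, cytokine, biogenesis and histone lists were not (0.2, 0.073, 0.0756 and 0.704).

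The remaining lists called on polysomes were oxidative phosphorylation (median 0.51), glycolysis (0.68), ribosomal proteins (0.35), translation factors (0.36), stress (0.35), heat shock (0.61) and smooth muscle markers (1.12), all higher with AUF1. Their adjusted p ran from 5.71e-08 for oxidative phosphorylation to 0.0256 for stress by camera, and from 0.147 for smooth muscle markers to 0.554 for oxidative phosphorylation and glycolysis with an estimated correlation. In edgeR, glycolysis had 2 members called (Pygm and Pgam2), heat shock had 1 (Hspb3), and the other 5 lists had 0. Members higher adjusted over the list alone were 3, 8, 0, 0, 0, 2 and 7, in the order given first, and 2 glycolysis and 1 heat shock genes were lower. With the block, members higher were 16 of 78, 8 of 26, 4 of 76, 4 of 40, 8 of 32, 3 of 18 and 6 of 10 in that order, and 3 glycolysis, 1 stress and 1 heat shock genes were lower. The stress list was not called without AUF1 polysome replicate 1 (adjusted p = 0.0667), nor translation factors without AUF1 polysome replicate 2 (0.062). The neuromuscular junction list had a median of 0.35 and was not called without the block (camera, adjusted p = 0.0656). With the block camera called it (adjusted p = 0.0202, and adjusted p = 0.517 with an estimated correlation), with 7 of 28 members higher and 2 lower in edgeR.

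Changes on polysomes and in total RNA were set side by side to ask whether polysome changes went with changes of total mRNA. The log2 fold changes had a Pearson's r of 0.93 and a Spearman's rho of 0.85 across 11159 genes, which are not independent replicates. All 46 genes called on polysomes were also called in total RNA in the same direction, 37 higher (0.303 for independent lists) and 9 lower (0.0178). With the block 1317 were shared, 708 higher (61.6 for independent lists) and 609 lower (51.3), and 0 went opposite ways in edgeR in either fit. The comparisons share no library, but both used 1 estimate of each gene's spread from all 8 libraries. A gene with a low spread is thus favoured in both, and the numbers for independent lists are too low as a reference. Total and polysome libraries of the same genotype and number may also come from the same culture. Between different numbers r was 0.75 (total of replicate 1 with polysome of replicate 2) and 0.86 (the reverse).

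The interaction of genotype and fraction asks whether AUF1 changed the polysome loading of an mRNA beyond its level. No gene passed: edgeR called 0 of 13167 genes, with 16 at an unadjusted p under 0.05 and a smallest adjusted p of 1, and the block gave 0, with 49 at an unadjusted p under 0.05. DESeq2 also called 0. Hnrnpd stood at -0.33 ± 0.43, Myog at -0.06 ± 0.40 and Myh3 at -0.69 ± 0.58. Data of this size were also simulated from the fit with the block, which favours the block. Of 100 genes with 4-fold interactions, 0% were recovered without the block and 66% with it, and the run with the block gave 12 false calls. In this setting the fit without the block also recovered 0% of 4-fold genotype changes, while it called 134 genes in total RNA in the data. The 0% for an interaction therefore does not measure the power of that fit. As sets, fast fibre genes (median -0.24, 14 of 17 members below 0) and sarcomere and Z-disc genes (median -0.18, 28 of 38 below 0) were lower by camera (adjusted p = 0.0372 for both), with 0 members called in edgeR, also adjusted over the list alone. Neither was called with the block (0.0846 and 0.122) or with an estimated correlation (adjusted p = 0.987 for both). Within replicates 1 and 2 the medians were -0.34 and -0.10 for fast fibre genes and -0.33 and -0.04 for sarcomere genes, and without WT total replicate 1 the sarcomere list turned up (adjusted p = 0.668). Without WT polysome replicate 2 the medians turned to 0.12 for sarcomere and 0.05 for fast fibre genes, while camera's direction stayed down (adjusted p = 0.743 and 0.89).

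Heavy polysomes were set against total RNA in WT cells to ask which mRNAs lie above or below the mean on polysomes. H19, an imprinted long noncoding RNA abundant in differentiating myoblasts (mm10 chromosome 7, 142575529 to 142578143), stood at 11455 ± 1434 CPM in total RNA and 2238 ± 109 CPM on polysomes (SD, n = 2 each). Sepw1, a small selenoprotein, stood at 315 ± 18.3 and 64.9 ± 3.58 CPM. These were the 2 genes called with the block, H19 at -2.36 ± 0.22 and Sepw1 at -2.28 ± 0.25 (adjusted p = 0.0231 for both), and both were chosen after their values were seen. Without the block edgeR called 0 of 13167 genes, with 364 at an unadjusted p under 0.05 and a smallest adjusted p of 0.331. DESeq2 called 30, all lower on polysomes. Hnrnpd stood at 0.53 ± 0.31.

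In WT cells camera called 8 lists. Ribosomal protein genes fell by a median of 0.69 on the log2 scale, with 67 of 76 below 0 (adjusted p = 1.99e-28; adjusted p = 0.133 with an estimated correlation), and snoRNA host genes, spliced RNAs that mostly encode no long protein, by 1.34, with 10 of 11 below 0 (4.88e-14; adjusted p = 0.133 with an estimated correlation). No member of either passed in edgeR over all genes, with or without the block, and 5 and 7 passed adjusted over the list alone. Examples are Rpl41 at -1.98 ± 0.31 (0.0952 with the block) and Snhg6 at -2.11 ± 0.36 (0.0952 with the block). Length of the coding region was not taken into account in either genotype, so lower values on heavy polysomes are not read as weaker translation. Glycolysis genes had a median of -0.45 (adjusted p = 4.25e-06; adjusted p = 0.676 with an estimated correlation), translation factors -0.26 (4.25e-06; adjusted p = 0.427 with an estimated correlation) and nuclear noncoding RNAs -0.41 (0.00713; adjusted p = 0.427 with an estimated correlation). Among them were Pfkp at -1.04 ± 0.28, Eif3f at -1.02 ± 0.25 and Neat1 at -0.80 ± 0.35. Of these 3 lists' members, only H19 was called with the block, and adjusted over the list alone 0, 0 and 1 were lower. H19 is held by the nuclear noncoding list, though it made up 0.225% and 0.257% of counts in the WT polysome libraries, whose molecule is cytoplasmic RNA. That list was not tested without it. Cell cycle genes (median -0.20) and heat shock genes (-0.23) were at the threshold (adjusted p = 0.0496 for both) and not called with the block (0.0997 and 0.117) or with an estimated correlation (adjusted p = 0.923 and 0.427). Myogenic regulators were higher, with a median of 0.22 and 19 of 22 above 0 (adjusted p = 0.0239, 0.0245 with the block; adjusted p = 0.923 with an estimated correlation), and 0 members were called. The myogenic list was not called without WT total replicate 1 (adjusted p = 0.753) or WT polysome replicate 2 (0.44), and the cell cycle list not without WT total replicate 2 (0.623) or WT polysome replicate 1 (0.337). The heat shock list was not called without WT total replicate 2 (0.276), WT polysome replicates 1 or 2 (0.156 and 0.0732) or AUF1 polysome replicates 1 or 2 (0.067 and 0.0837).

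The same comparison in AUF1 cells gave H19 and Sepw1 as the 2 genes called with the block. H19 stood at 17995 ± 2037 CPM in total RNA and 2868 ± 179 CPM on polysomes (log2 change -2.65 ± 0.22, adjusted p = 0.0181 with the block), and Sepw1 at -2.24 ± 0.25 (0.024 with the block). Without the block edgeR called 0 of 13167 genes, with 438 at an unadjusted p under 0.05 and a smallest adjusted p of 0.172, and DESeq2 called 29, all lower on polysomes. Hnrnpd stood at 0.21 ± 0.30. Camera called 5 lists, all lower on polysomes. Ribosomal protein genes had a median of -0.59, with 64 of 76 below 0 (adjusted p = 9.56e-21; adjusted p = 0.23 with an estimated correlation), and snoRNA host genes -1.32, with 10 of 11 below 0 (4.33e-11; adjusted p = 0.23 with an estimated correlation). Glycolysis genes had a median of -0.60 (1.12e-05), sarcomere and Z-disc genes -0.29 (0.00146) and translation factors -0.19 (0.00146), each with adjusted p = 0.677 with an estimated correlation. Members called in edgeR were 0 in all 5 lists, and adjusted over the list alone 1 ribosomal and 8 snoRNA host genes were lower and 0 of the other 3 lists. Rpl41 stood at -2.19 ± 0.32, Snhg6 at -1.93 ± 0.36, Unc45b at -1.28 ± 0.29 and Eef2, elongation factor 2, at -1.08 ± 0.22 (0.0568, 0.122, 0.2 and 0.247 with the block). The glycolysis list was not called without AUF1 total replicate 1 (adjusted p = 0.209), and the sarcomere and translation lists not without AUF1 total replicate 2 (0.198 and 0.232) or AUF1 polysome replicate 1 (0.16 and 0.135).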

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

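Of the tests in this part, those of the AUF1 total library of replicate 1 and of GC content were chosen only after the lists were seen to differ, and the first was repeated with the replicate block after its value without the block was seen. A difference between the fractions in the effect of AUF1 was found for 2 gene lists by a test of the interaction. Fast fibre genes had a median log2 interaction of -0.24 and sarcomere and Z-disc genes of -0.18 (limma camera, adjusted p = 0.0372 for both, 14 of 17 and 28 of 38 members below 0). Neither list was called with the replicate block (adjusted p = 0.0846 and 0.122) or with an estimated correlation (adjusted p = 0.987 for both). In edgeR 0 of 13167 single genes passed, with 16 at an unadjusted p under 0.05, and DESeq2 called 0.

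Muscle structural mRNAs rose in both fractions, and a smaller rise on heavy polysomes is open, with a median interaction of -0.20 over the 52 genes of both lists and, within replicates 1 and 2, medians of -0.33 and -0.04 for sarcomere genes and -0.34 and -0.10 for fast fibre genes. The AUF1 total library of replicate 1 cannot be told apart from an effect of AUF1, since without it the median over both lists was -0.20 without the block, where the split by replicate number enters, and 0.0252 with the block (sarcomere adjusted p = 0.00705 and 0.523, fast fibre 0.34 and 0.957), and without WT polysome replicate 2 it was 0.12 without and 0.00146 with the block. With the block neither list was called with all 8 libraries, and leaving out 1 changed that for both without WT total replicate 2 (adjusted p = 0.00394 for sarcomere and 0.0189 for fast fibre genes), for the sarcomere list without AUF1 polysome replicate 1 (0.0224), and for the fast fibre list without AUF1 total replicate 2 (0.00788), WT polysome replicate 1 (0.0089) or AUF1 polysome replicate 2 (0.0479). Without the block neither was called without WT total replicate 1 (0.668, with the sign turned, and 0.566), AUF1 total replicate 2 (0.431 and 0.143), WT polysome replicate 2 (0.743 and 0.89, where the medians turned to 0.12 and 0.05 while camera's direction stayed down) or AUF1 polysome replicate 1 (0.531 for both). GC content of the transcripts cannot be told apart from an effect of AUF1 either, since after a GC correction with the block the median was -0.0543, with an unadjusted camera p of 0.0494 for the sarcomere list and adjusted p = 0.667 for both lists.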

How the results depend on the processing

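Among the alternatives of this part, the block with GC correction, the block with each library left out (for genes and for lists), scaling without the 50 most abundant genes and the corrected histone list were chosen only after the data were seen. Of the counts and set results, 146 values under alternatives stayed within 1.5 times or on the same side of the threshold, 113 moved and 1 reversed. A count of 0 that stayed at 0 is among the 146. A log2 fold change of at least 1 could not move the counts, since each called gene already changed at least 2-fold. The 146 therefore do not measure how stable the called genes were. For the named genes called in total or polysome RNA (65 values, 1170 values under alternatives), 364 kept their call, 806 lost it and 0 turned. The cause was not tested unless given.

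The 134 genes called in total RNA, the 46 on polysomes and the 46 shared became 0, 0 and 0 in edgeR with DESeq2 size factors, with upper-quartile factors, with only the compared groups (fewer residual degrees of freedom), and with total counts without the 50 most abundant genes, which moved the median of all genes to -0.13 in total RNA. A CPM of at least 1 in 2 libraries gave 0 on polysomes and 0 shared. At an unadjusted p under 0.05 the planned model had 1807 and 1862 genes. No filter on low counts gave 94 on polysomes, 92 shared and 1 for polysome against total RNA with AUF1. Limma voom gave 102 on polysomes and 88 shared. DESeq2 gave 885, 856 and 675 shared, and 30 and 29 for polysome against total RNA in WT and AUF1, where edgeR called 0 and 0 (364 and 438 at an unadjusted p under 0.05). The replicate block gave 1730, 1716, 1317 shared, 2 and 2, the block within genotype 1 for polysome against total RNA with AUF1, and the block with GC correction 2566, 2714, 2140 shared, 11 and 8. A smaller SE with the block (0.27 against 0.38) goes with the larger counts by its construction, since it removes the split by number. The interaction, not run with only the compared groups or without the 50 most abundant genes, stayed at 0 genes in the other fits named (edgeR 16 and DESeq2 16 at an unadjusted p under 0.05).

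Leaving out 1 library, with the lone library of its group assumed to vary like the others, gave 0 to 2975 genes in total RNA, 0 to 3011 on polysomes and 0 to 1576 shared. Without the block each of the 8 left 0. With the block the counts in total RNA, on polysomes and shared were 329, 1178 and 326 without WT total replicate 1, 628, 1226 and 594 without WT total replicate 2, 1204, 3011 and 1155 without AUF1 total replicate 1, and 2975, 2802 and 1576 without AUF1 total replicate 2. They were 2175, 1130 and 936 without WT polysome replicate 1, 2178, 1424 and 1227 without WT polysome replicate 2, 1522, 592 and 579 without AUF1 polysome replicate 1, and 1649, 949 and 813 without AUF1 polysome replicate 2.

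The lists called numbered 16 in total RNA, 17 on polysomes, 2 for the interaction, and 8 and 5 for polysome against total RNA in WT and AUF1. With an estimated correlation they numbered 0, 0, 0, 0 and 0, and with fry, which does not compare a list with other genes, 7, 7, 0, 2 and 1. Those called by fry in total RNA and on polysomes were all higher with AUF1. Fry did not call the matrix, fibroblast and cytokine lists (adjusted p = 0.634, 0.468 and 0.135 in total RNA, 0.614, 0.441 and 0.228 on polysomes). With the block its adjusted p was 0.058, 0.0432 and 0.0265 in total RNA and 0.0479, 0.0417 and 0.0417 on polysomes. By camera, 0 lists were called for the interaction with the block, with no filter and with the block and GC correction, and the last gave 5 in WT. Leaving out 1 library gave 2 to 6 for the interaction, with 6 without WT total replicate 2, AUF1 total replicate 1 or WT polysome replicate 1 and 5 without either AUF1 polysome library, and 6 to 12 for polysome against total RNA with AUF1, with 8 without AUF1 total replicate 1 and 12 without AUF1 polysome replicate 2. With the block these were 5, 4, 5, 5, 4, 3, 5 and 4 for the interaction, leaving out WT total, AUF1 total, WT polysome and AUF1 polysome replicates 1 and 2 in turn, and 4 (without WT total replicate 2) to 9 (without AUF1 total replicate 2 or AUF1 polysome replicate 1) for polysome against total RNA with AUF1. No filter ended the calls of the neuromuscular junction and fibroblast lists in total RNA (adjusted p = 0.0524 and 0.0706) and of the myogenic regulator list in WT (0.0852). DESeq2 size factors ended that of heat shock genes in WT (0.0525), and the block with GC correction those of nuclear noncoding RNAs (0.0602), cell cycle (0.125) and heat shock genes (0.0926) in WT and of histones on polysomes (0.0842). With the block and 1 library left out, calls of lists also ended on polysomes for stress genes without WT polysome replicate 1 (0.0525) and for mitochondrial biogenesis without AUF1 polysome replicate 1 (0.0642) or WT polysome replicate 2 (0.0533). They ended in WT for glycolysis without WT polysome replicate 1 (0.0633) and for myogenic regulators without WT total replicate 1 (0.188) or WT polysome replicate 2 (0.0778), and with AUF1 for glycolysis without AUF1 total replicate 1 (0.109). With AUF1 they also ended for sarcomere genes without AUF1 total replicate 1 (0.0616) or AUF1 polysome replicate 2 (0.0771), and for translation factors without AUF1 total replicate 2 (0.119), AUF1 polysome replicate 2 (0.0771) or WT total replicate 2 (0.0513). Without H13 and H19 the histone list ended its call on polysomes, where 16 lists were left. The AU-rich set on polysomes turned from 0.00528 to -0.0296 with strata of UTR AT content (permutation p = 0.00547). With 25281224 to 34917660 counts per library, depth limits genes with few counts, and over all genes the spread between the replicate numbers exceeded counting error (chi-square per gene from 341 to 513).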

Other observations

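Of the tests in this part, those of the loss of endoplasmic reticulum and of cycling cells were chosen only after the result was seen, and those of Wnt readouts, GC content, transcript length, depth and scaling after the patterns they address were noticed. Only the test of AU-rich heptamers was planned.

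As a set, mRNAs of proteins made on the endoplasmic reticulum were higher in replicate 1 than in replicate 2 in all 4 groups. How many of the separating genes encode such proteins was not counted. Bsg, a plasma membrane glycoprotein, had a ratio of replicate 1 to replicate 2 of 18.2 in WT total, 18.4 in AUF1 total, 26.2 in WT polysome and 23.5 in AUF1 polysome RNA, and the lysosomal protease Ctsd of 16.5, 16.7, 13.5 and 13.3. Actb, translated in the cytosol, had 1.05, 1.36, 0.85 and 0.959, and Neb, which encodes the giant sarcomere protein nebulin, went the other way, with 0.278, 0.137, 0.475 and 0.677. In lists written from general knowledge, the 70 mRNAs of secreted, lysosomal, membrane and reticulum proteins, with the genes of the largest differences left out, exceeded the 66 of cytosolic and nuclear proteins by a median log2 ratio of 2.45, 2.46, 2.13 and 2.35 in these groups (folds of 5.46, 5.52, 4.39 and 5.08).

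Sequencing depth is argued against as the source, since the 2 WT total libraries differed in depth by 1.78% and still differed by 2.45 between the lists. GC content and transcript length are argued against too, since the lowest of the 4 differences was 2.02 after regression on both. A candidate explanation is a loss of mRNA bound to the endoplasmic reticulum when the libraries of replicate 2 were prepared, for example in lysis. The lowest of the 4 differences, 2.13, restates the pattern it was drawn from and would follow from a difference in the state of the cultures too, so these cannot be told apart, and the labels give no batch or date to test them. Chrna1, the acetylcholine receptor subunit that the neuromuscular list holds, had ratios of 8.35, 13.9, 7.63 and 14.1, so its change with AUF1 can be read only within a replicate number, where it was 1.48 and 0.74 in total RNA.

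Muscle structural genes were higher with AUF1 in both fractions, and the size of this change did not come from scaling by abundant genes, since without the 50 most abundant genes the lower of the 2 medians of the sarcomere list was 2.15. GC bias of the libraries is argued against as well, with a lower median of 2.22 after GC correction. Fewer cycling cells in the AUF1 cultures would bring the cell cycle list down in both fractions. With the block its median was 0.0624 in total RNA and 0.27 on polysomes. The SE of the first, 0.0955, is over 42 genes and does not measure the spread between cultures. The list went opposite ways in replicates 1 and 2, with 0.62 and -0.35 in total RNA and 0.66 and -0.23 on polysomes. The medians therefore do not decide whether fewer cells were cycling, and a difference in growth within a replicate stays open. Fibroblast markers (medians of -1.99 in total RNA and -1.91 on polysomes) and matrix genes (-0.86 and -0.84) were lower with AUF1 as muscle genes were higher, and whether the share of cell types or expression within cells differed was not tested.

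Axin2 and Nkd2, feedback inhibitors of Wnt signalling, fell with AUF1 in total RNA, and Sfrp2, a secreted Wnt modulator, stood at 341 ± 389 CPM in WT and 1.28 ± 0.92 CPM in AUF1 total RNA (SD, n = 2 each; log2 change -8.05 ± 1.67, edgeR adjusted p = 0.101, 0.0002 with the block; -8.27 and -6.57 within replicates 1 and 2). Igf1, the insulin-like growth factor gene, stood at -4.76 ± 0.95 (0.0015 with the block). Lower canonical Wnt signalling may go with these falls. Among 23 other readout genes the median was -0.56 in total RNA (camera, unadjusted p = 0.00327) and -0.45 on polysomes (0.000757), where -0.5 in both had been set as the mark, so the set does not decide it. The set was not tested with an estimated correlation, with which no fixed list was called. With the block 0 were higher and 5 lower in total RNA and 0 and 4 on polysomes. Dkk2, Fzd7, Tnfrsf19, Sox9, Fst, Porcn and Plaur were above 0 in both fractions. Lgr5, a receptor that amplifies Wnt signals, stood at -5.26 and -5.17 and Notum, which inactivates Wnt proteins, at -2.27 and -3.45, while Lef1 stood at -0.22 and -0.24. Tcf7 stood at -1.10 and -1.29. A lower share of a cell population with high Wnt activity would look alike, and was not tested.

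AUF1 binds AU-rich elements, so mRNAs with the heptamer TATTTAT in the 3' UTR were compared as a set. Of the mRNAs tested, 3257 held it and 7102 did not. Within deciles of UTR length, those with it were set against the mean of all mRNAs of their decile, themselves included. The mean log2 difference was -0.0322 in total RNA (permutation p = 0.0017) and 0.00528 on polysomes (permutation p = 0.596). The size of 0.1 set beforehand was for a difference from mRNAs without the heptamer. A difference from the decile mean is a smaller measure, since that mean includes the mRNAs with it. These values therefore do not decide whether the mRNAs changed by 0.1 as a set, nor whether some of them changed. The interaction differed from the decile mean by 0.04 (permutation p = 1e-05, the smallest these resamples can give). Without strata, the mean with the heptamer less the mean without it was -0.15 in total RNA, -0.03 on polysomes and 0.12 for the interaction. That is another measure, so the part that went with UTR length was not determined. With at least 3 ATTTA pentamers the differences from the decile mean were -0.07, 0.01 and 0.08 (permutation p = 1e-05, 0.167 and 1e-05). In genes with a mean log2 CPM of at least 4 they were -0.02, 0.01 and 0.03 (permutation p = 0.0261, 0.332 and 1e-05). With strata of UTR AT content in place of length they were -0.05, -0.03 and 0.02, so the polysome difference turned (permutation p = 1e-05, 0.00547 and 1e-05). Genes are not independent replicates here, and these p-values cover the assignment of heptamers to genes, not the spread between cultures. The fold changes used were not corrected for GC content of the transcripts. Differences between replicates 1 and 2 went with GC content in the WT and AUF1 total pairs (Spearman's rho 0.38 and 0.56). In both polysome pairs rho was 0.02. A GC bias of the libraries and an effect of AUF1 on these mRNAs therefore cannot be told apart.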
